A study of Mus musculus with 4 samples.

How the data were processed

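Immune cells were profiled by droplet single-cell 3' RNA sequencing (10x Genomics) from B16F10-OVA tumours, a mouse melanoma line carrying the model antigen ovalbumin. The host mice were wild-type C57BL/6 or miR-155 T cell conditional knockout mice, and tumours were taken 9 or 12 days after subcutaneous injection. Per the labels, the tumours of a group were pooled, live CD45-positive cells were sorted, and equal numbers of sorted cells were processed. This gave 4 libraries with 1 library per genotype and day, so no group has replicates. Preparation runs are not given in the labels, and day and preparation run cannot be told apart. The share of a class depends on the sorting and on equal loading of cells.

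The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 2.0.2 on the mm10 genome per the submitters' processing notes, for barcodes already filtered by that tool. The files pair 27998 gene IDs with symbols, and 27645 of these IDs have a position in GENCODE vM21, whose transcripts were used for 3' UTRs and positions.

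Cells were kept with at least 200 genes, with at most 10% of UMIs from mitochondrial genes and with at most 5% from haemoglobin genes. The haemoglobin limit was set after the data were seen and removed 2 barcodes. Doublet scores came from Scrublet as carried by scanpy, and the highest scores were removed at an assumed rate of 0.8% per 1000 barcodes. Scrublet's own threshold called 2, 6, 1 and 15 barcodes, which is under the expected 1.42%, 2.99%, 2.94% and 1.63% of wild-type and knockout at day 9 and wild-type and knockout at day 12. The numbers removed were 25, 112, 108 and 33.

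Counts were scaled to 10000 per cell and logged. The 2000 most variable genes, 30 principal components and 15 neighbours gave Leiden clusters at resolution 1. Cells of the T cell and NK cell clusters were clustered again together at resolution 2, and myeloid cells kept their clusters of resolution 1. A cluster took the name of a class from lists of marker genes fixed before the data were examined. A marker counted when its mean reached 0.5 per 10000 UMIs and was at least 2-fold over the median of the clusters, and at least 3 markers were needed. A cluster could also be left unnamed where markers of another class led its top 10 genes. CD8 T cells needed a Cd8b1 mean of 5 per 10000 UMIs and CD4 T cells a Cd4 mean of 0.7, and the Cd8b1 threshold was set after the data were seen. Class names stand for cells with the markers of that class, such as CD8 T cell-like clusters, and T cells in none of the named groups are called other T cells. Clusters without a name were kept in the totals as unnamed.

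UMIs were summed per class and library and scaled to UMIs per 1000000 UMIs of that class (CPM). Log2 ratios used 0.5 added UMIs per gene in lists, correlations and seed comparisons, and the plain counts for single named genes with their intervals. A ratio was used when the gene had at least 20 UMIs over the pair of libraries. The 6 classes with at least 50 cells in every library were compared in expression: CD8 T cells, other T cells, natural killer (NK) cells, conventional dendritic cells 1 and 2 (cDC1 and cDC2), and monocytes or macrophages. Lists of genes were fixed before the data were examined: cell cycle, interferon-gamma response, type I interferon response, MHC class I presentation, MHC class II presentation, cytotoxic and effector T cell, inhibitory receptor, naive and memory T cell, regulatory T cell activation, inflammatory macrophage, alternatively activated macrophage, chemokine, hypoxia and glycolysis, lipid and lysosome macrophage, dissociation and stress, reported miR-155 target, respiratory chain and sex-linked. For each list the members at least 1.5-fold higher or lower were counted. The median log2 ratio was placed among 10000 random lists of the same size matched on expression in 20 bins, and a 95% interval for counting error came from 1000 draws.

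Intervals on shares are 95% Clopper-Pearson intervals, those on UMI counts exact Poisson intervals, and those on ratios of counts exact conditional intervals. They cover counting error only and not the difference between mice, pools or preparations. P-values come only from a fit across genes of the 4 class sums with day and genotype as terms (edgeR 4.0.16 quasi-likelihood test, TMM factors, filterByExpr, Benjamini-Hochberg adjustment, adjusted p 0.05). This fit has 1 residual degree of freedom. Its prior degrees of freedom were infinite in NK cells and from 6.08 to 21.03 in the other classes. NK cell calls thus rest on variation pooled over genes and do not compare directly with those of other classes. The fit tests a genotype effect common to both days and a day effect common to both genotypes. Correlations of genotype ratios between days are across genes, which are not independent replicates, and were set beside 20 simulations with counting noise alone.

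For sites of miR-155, the longest annotated 3' UTR of each of 20781 genes was searched for the reverse complement of seed bases 2 to 8, AGCATTA, and 1801 genes had a site. The median log2 ratio of genes with a site minus that of genes without was set beside the same difference for other sequences of 7 bases. These were all 419 other sequences with the same base composition, in place of the 1000 planned. They were not matched on the number of genes with a site.

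Genes are named by a rule fixed before the data were examined. It names the deleted gene. In each class it names the 5 genes per direction with the largest smaller change over both days, with at least 20 UMIs at each day and 50 CPM in 1 library of each day, leaving out mitochondrial, ribosomal protein, immunoglobulin, T cell receptor, haemoglobin and sex-linked genes and markers of other classes. In each list it names up to 2 members with the highest CPM and 2 with the largest ratio, and in each fit the 5 per direction with the largest fold past adjusted p 0.05. Of these, the text gives a part. Genes named outside the rule are said to be chosen after their values were seen.

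The alternatives were mitochondrial shares up to 5%, at least 500 genes per cell, no doublet removal, resolutions 0.5 and 2, classes from each cell's own markers, clustering without cell-cycle genes, TMM and median-of-ratios scaling, the mean over cells, cells thinned to 2500 UMIs, members with at least 5 UMIs or 2-fold, DESeq2 1.42.0, no gene filter, no day term and each library left out. After the data were seen, CD8 T cells outside the clusters with Dapl1 among their top 10 genes, and monocytes or macrophages without the cluster with the most melanoma transcripts, were added, as were regulatory T cells with the unnamed cluster that has their markers among its top 10 genes. That cluster stayed unnamed because markers of myeloid cells led it among lymphoid cells. Resolutions 0.5 and 2 were those of the first clustering, and T cells and NK cells were always clustered again at resolution 2.

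Each method was tested on simulated data. With a dispersion of 0.01 the fit found from 83% to 94% of 2-fold changes over the 6 classes, and with a dispersion of 0.1 from 0% to 8%. Random lists raised 1.5-fold were placed at the 100.0 percentile, 6% of unchanged lists fell outside the middle 95%, and counting intervals held the true value in 95% of draws. A seed effect of 0.3 was found as 0.301. Tools were Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, biopython 1.88, matplotlib 3.10.9 and R 4.3.3.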

Results

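Transcripts of single live CD45-positive cells were counted in 4 libraries from subcutaneous B16F10-OVA melanomas. The tumours had grown from 1000000 injected cells in wild-type C57BL/6 mice or in mice lacking miR-155 in T cells (miR-155 TCKO, called knockout here). Tumours were taken at day 9 and day 12 and pooled per group from more than 4 mice. The library of wild-type tumours at day 9 held 1778 cell barcodes with 21448114 UMIs and a median of 9655 UMIs per barcode. The knockout library at day 9 held 3749 barcodes with 33902064 UMIs and a median of 7747. At day 12 the wild-type library held 3684 barcodes with 29662903 UMIs and a median of 7379, and the knockout library held 2059 barcodes with 18783490 UMIs and a median of 7770. After filtering, 1752, 3625, 3565 and 2002 cells remained in the same order. The median mitochondrial share of the cells kept lay between 1.68% and 1.93%.

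There were no replicates, as each genotype and day had 1 library, so differences at 1 day are given with 95% intervals that cover counting error only. Calls come from edgeR's quasi-likelihood test on day and genotype over the 4 libraries. Of the sex-linked genes, Xist had 0 UMIs in CD8 T cells of all 4 libraries, and the sex-linked list had a median log2 ratio, knockout over wild-type, of 0.24 (-0.08 to 0.61) in monocytes or macrophages at day 9.

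The deleted gene was read first. Mir155hg (ENSMUSG00000097418; mm10, chromosome 16, 84703167 to 84715245, plus strand) is the host transcript of miR-155. T cells of the wild-type libraries held 91 Mir155hg UMIs at day 9 and 24 at day 12, and T cells of both knockout libraries held 0. An UMI count of 0 allowed up to 0.892 CPM at day 9 and 3.51 CPM at day 12, against 8.34 CPM (6.72 to 10.2) and 9.05 CPM (5.80 to 13.5) in wild-type T cells. Had each CD8 T cell cluster kept its wild-type rate, 9.01 UMIs would have been found in CD8 T cells of both knockout libraries, and the chance of 0 was 0.0122%. Cells other than T cells kept the transcript. Mature dendritic cells held 12 and 61 Mir155hg UMIs in the knockout libraries at day 9 and day 12, and NK cells held 4 and 12. A 3' tag may lie outside the deleted part of a gene, which limits what a count can show.

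The first comparison asked how the loss of miR-155 in T cells went with the mix of immune cells in the tumour. CD8 T cells, which kill tumour cells, formed a smaller part of the knockout infiltrate at both days. At day 9 the knockout infiltrate held mostly monocytes or macrophages, and it held few cDC1, the dendritic cells that present antigen to CD8 T cells. At day 12 monocytes or macrophages were the class with the most cells in both genotypes, and mature dendritic cells formed a larger part of the knockout infiltrate.

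CD8 T cells made up 39.1% (36.8 to 41.4) of wild-type and 9.05% (8.13 to 10.0) of knockout cells at day 9, a ratio of 0.231 (0.202 to 0.264). At day 12 they made up 6.48% (5.69 to 7.34) and 2.75% (2.08 to 3.56), a ratio of 0.424 (0.310 to 0.571). There were 2.5, 0.172, 0.128 and 0.0580 CD8 T cells per monocyte or macrophage in wild-type and knockout at day 9 and wild-type and knockout at day 12. Monocytes or macrophages made up 15.6% (14.0 to 17.4) and 52.6% (51.0 to 54.3) at day 9, and 50.5% (48.8 to 52.1) and 47.4% (45.1 to 49.6) at day 12. NK cells were at 12.4% against 7.03% at day 9, a ratio of 0.565 (0.470 to 0.681), and at 14.4% and 14.7% at day 12. The share of cDC1 was 7.71% against 1.38% at day 9, a ratio of 0.179 (0.127 to 0.249) that became 0.451 when each cell was named by its own markers, and 5.41% against 5.44% at day 12. Mature dendritic cells, which carry antigen to lymph nodes, were at 2.63% against 1.71% at day 9 and at 3.03% against 8.49% at day 12, with ratios of 0.651 (0.438 to 0.976) and 2.80 (2.19 to 3.60). Regulatory T cells were at 2.00% against 0.359% at day 9 and at 1.29% against 1.20% at day 12. There were 19.6, 25.2, 5.02 and 2.29 CD8 T cells per regulatory T cell in the order above. The intervals at day 9 overlapped, at 13.9 to 28.3 in wild-type and 14.5 to 47.9 in knockout, the latter from 13 regulatory T cells. An unnamed cluster with Foxp3, Ctla4 and Il2ra among its top genes held 52, 47, 10 and 5 cells, and it carried myeloid transcripts too, with Lyz2 at 2658 CPM against 189 CPM in regulatory T cells. Its wild-type cells of day 9 held Foxp3 at 23.5 CPM and Cd8b1 at 563 CPM, against 213 and 343 CPM in named regulatory T cells. Many of them may thus not be regulatory T cells. With that cluster, a choice made after the data were seen, regulatory T cells were at 4.97% against 1.66% at day 9 and at 1.57% against 1.45% at day 12. CD8 T cells per regulatory T cell were then 7.87, 5.47, 4.13 and 1.90, so the order at day 9, which lay within counting error, turned. Plasmacytoid dendritic cells were at 2.17% against 6.37% at day 9, and 231 of these cells came from the knockout library of that day.

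Because shares add up to the whole, non-T cells were also counted alone. Among them at day 9, NK cells were at 24.1% in wild-type and 8.97% in knockout, cDC1 at 14.9% and 1.76%, and monocytes or macrophages at 30.3% and 67.1%. At day 12, NK cells were at 17.0% and 16.6% of non-T cells, cDC1 at 6.37% and 6.13%, and mature dendritic cells at 3.56% and 9.56%. Other T cells, mainly 1 cluster with Ikzf2 and Klra6 transcripts, were at 6.22% against 9.46% of all cells at day 9 and at 5.27% against 5.89% at day 12, and their ratio at day 12 of 1.12 became 0.879 when cell-cycle genes were left out of clustering. The share of cDC2 was 5.31% against 5.96% at day 9 and 9.28% against 9.14% at day 12. CD4 T cells were at 1.03% against 2.68% at day 9, a ratio of 2.60 that became 0.742 when each cell was named by its own markers. B cells were at 0.343%, 0.497%, 0.253% and 0.799% of the libraries. Unnamed clusters, among them the one with Foxp3 and myeloid transcripts, 1 with Il1rl1, Areg and Gata3 and 1 with S100a8 and S100a9, held 5.42%, 2.87%, 1.46% and 1.95%.

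**Figure D1:**
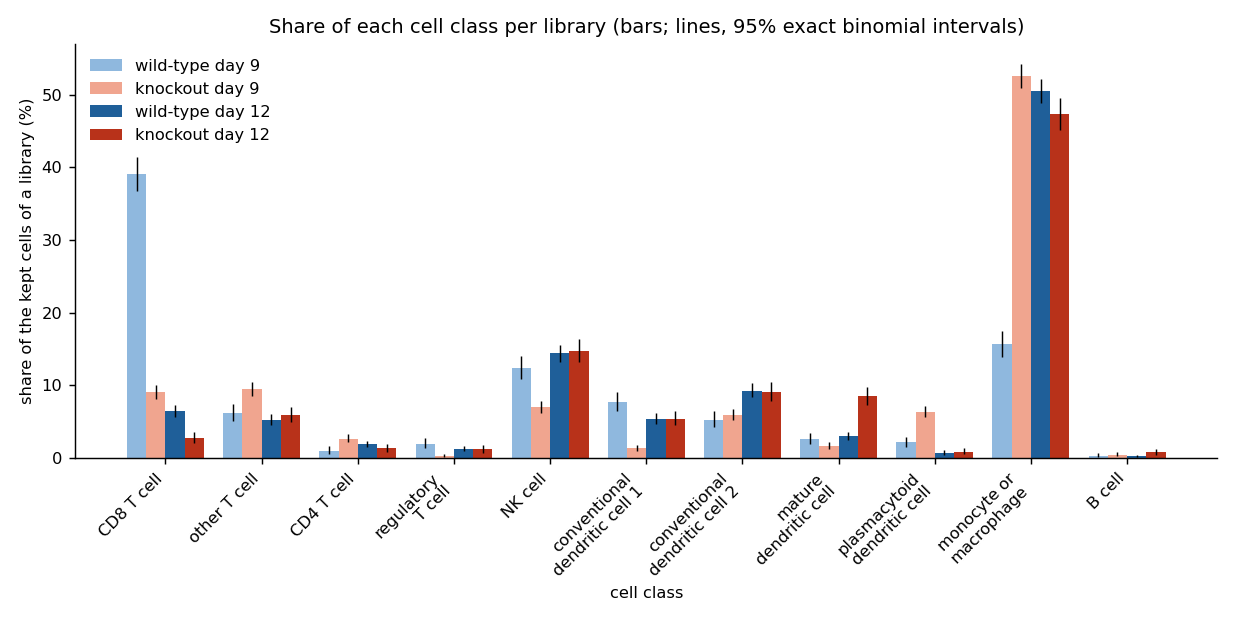
Share of each cell class (x axis) among the kept cells of a library in percent (y axis), as bars with 95% Clopper-Pearson intervals as lines, for the 4 libraries. CD8 T cells stand at 39.1% of the wild-type library of day 9 and at 9.05%, 6.48% and 2.75% of the others.

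The next comparison asked what the CD8 T cells that were present expressed. Knockout CD8 T cells carried less transcript of cell division, killing and inhibitory receptors, and more transcript of naive and memory T cells. This held at both days. The same difference appeared as a shift between clusters. Of 2 clusters with Dapl1, 1 also had Igfbp4, Lef1 and Tcf7 and 1 had the interferon-induced genes Ifit1 and Ifit3. They held most knockout CD8 T cells, while clusters with Gzmk, Pdcd1 and Tox, or with cell-division genes, came mostly from the wild-type library of day 9.

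Clusters with Dapl1 among their top genes held 8.76% and 79.6% of wild-type and knockout CD8 T cells at day 9, and 23.8% and 67.3% at day 12. The cluster with Gzmk, Pdcd1, Tox and Lag3 held 247, 4, 22 and 0 cells of the 4 libraries, and the 3 clusters with cell-division genes held 103, 3, 17 and 0 cells, 50, 2, 4 and 0 cells, and 131, 11, 13 and 2 cells. CD8 T cells had a median of 12146 UMIs in the wild-type library of day 9 and of 4923, 4673 and 4354 in the others.

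In CD8 T cells at day 9 all 24 cell-cycle genes were at least 1.5-fold lower in knockout, with a median log2 ratio of -1.56 (-1.64 to -1.43), and at day 12 19 of 24 were lower, with a median of -1.52 (-1.89 to -1.20). Mki67, a marker of dividing cells, had a log2 ratio at day 9 of -2.23 (-2.69 to -1.81). Cytotoxic and effector genes were lower for 17 of 24 and higher for 4 at day 9, with a median of -0.98 (-1.14 to -0.87), and lower for 13 of 20 and higher for 2 at day 12, with a median of -0.79 (-1.06 to -0.57). Among them Nkg7 had log2 ratio -1.21 at day 9, Gzmk -3.92 and -3.19 at day 9 and day 12, and Ifng, the interferon-gamma gene, stood at 489 against 315 CPM at day 9 and at 209 against 1465 CPM at day 12. Inhibitory receptors were lower for 13 of 16 at day 9, with a median of -1.43 (-1.56 to -1.08), and for 8 of 13 at day 12, with a median of -0.69 (-1.13 to -0.37). Pdcd1, which encodes PD-1, was at 120 against 429 CPM at day 9. Naive and memory genes were higher for 14 of 17 at day 9, with a median of 2.97 (2.75 to 3.02), and for 12 of 16 at day 12, with a median of 1.28 (1.01 to 1.44). Klf2 had log2 ratios of 3.12 and 1.33, and Dapl1 of 3.09 and 1.95. These 8 medians lay beyond the middle 95% of random lists.

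**Figure D2:**
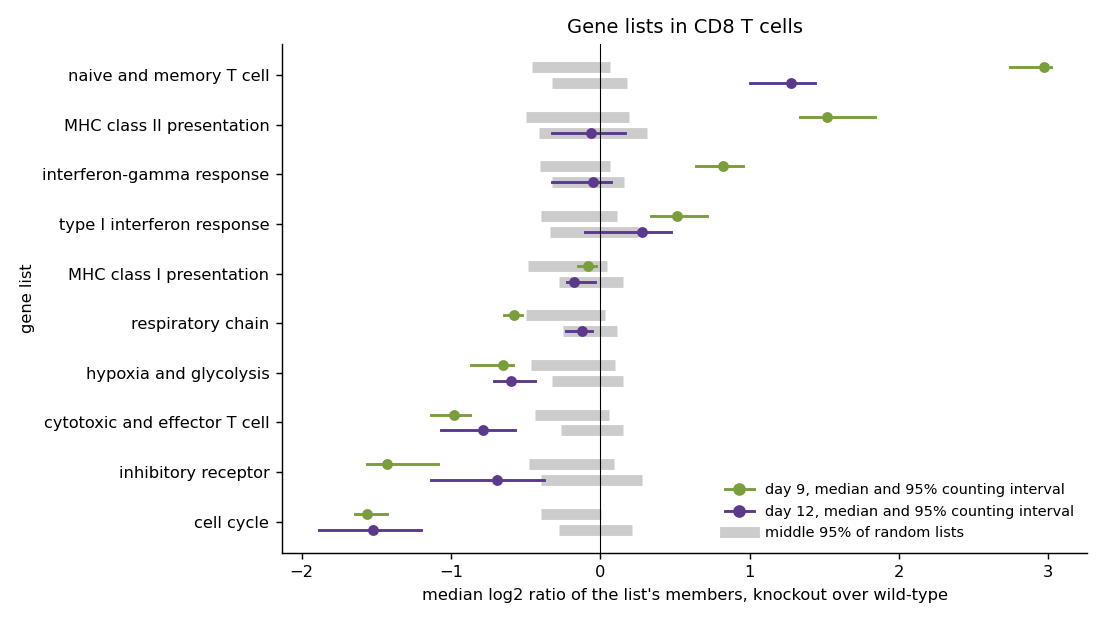
Median log2 ratio of the members of a gene list in CD8 T cells, knockout over wild-type (x axis), for 10 gene lists (y axis) at day 9 and day 12, with 95% counting intervals as lines and the middle 95% of random lists as grey bars. Cell-cycle genes stood at -1.56 and -1.52, and naive and memory genes at 2.97 and 1.28.

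Outside the Dapl1 clusters, chosen after the data were seen, the medians at day 9 were -0.31 for cell cycle, -0.36 for cytotoxic and effector genes, -0.37 for inhibitory receptors and 1.65 for naive and memory genes, and at day 12 they were -0.61, -0.56, -0.01 and 0.25. Over both days, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment found that 20 of 24 cell-cycle genes fell (23 adjusted over the list alone), 8 of 21 cytotoxic and effector genes fell (13 adjusted over the list alone, with 1 that rose), 8 of 15 inhibitory receptors fell (8 adjusted over the list alone) and 14 of 17 naive and memory genes rose (14 adjusted over the list alone). Igfbp4 rose with a log2 fold change of 4.88 (adjusted p 5.57e-05 in this test), and Hist1h2ae and Entpd1 fell with log2 fold changes of -3.79 and -3.94 (adjusted p 2.57e-04 and 1.05e-03). Igfbp4, Jun and Socs3 were higher at both days, with log2 ratios of 5.39 and 3.60, 2.38 and 2.16, and 3.39 and 1.97. Hist1h1b and Ube2c were lower at both days, with log2 ratios of -2.04 and -1.97 at day 9.

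Other lists were read in CD8 T cells as well. Hypoxia and glycolysis genes were lower for 12 of 21 at day 9 and for 11 of 19 at day 12, with medians of -0.65 and -0.60, among them Gapdh at -1.07 and -0.99, and the medians were 0.08 (-0.12 to 0.20) and -0.23 (-0.43 to 0.01) outside the Dapl1 clusters. Respiratory chain genes were lower for 11 of 23 at day 9, with a median of -0.58, and for 0 of 23 at day 12, and outside the Dapl1 clusters for 0 of 23 at day 9, with a median of -0.20. The edgeR test called 0 of 23 of them, and 0 adjusted over the list alone. The interferon-gamma response list had a median of 0.82 (0.64 to 0.96) at day 9, with 16 of 27 genes higher, and of -0.05 (-0.32 to 0.07) at day 12, while Psmb8 was lower at -0.24 at day 9. Outside the Dapl1 clusters its median at day 9 was 0.00 (-0.16 to 0.16), with 8 of 26 higher, and at day 12 -0.25 (-0.62 to -0.07). The type I interferon response list had a median of 0.52 at day 9, with 10 of 22 genes higher, which became -0.37 with mitochondrial shares up to 5%, -0.47 without doublet removal and -0.75 outside the Dapl1 clusters. The Dapl1 clusters include the one with Ifit1 and Ifit3, which also carried Ncr1. MHC class II genes were higher for 9 of 10 at day 9, with a median of 1.52, and had a median of -0.06 at day 12, beside macrophage transcripts (C1qa, C1qb and Apoe) at 7.73 and 37.3 CPM in wild-type and knockout at day 9 and at 106 and 104 CPM at day 12. MHC class I genes had medians of -0.08 and -0.17, and the first became 0.00 with TMM and 0.07 with median-of-ratios scaling. These 2 scalings raised all log2 ratios of that comparison by 0.09 and 0.15. Dissociation and stress genes had medians of 0.18 and 0.37, and of 0.64 and 0.82 outside the Dapl1 clusters, and edgeR's quasi-likelihood test found that 6 of 15 rose (7 adjusted over the list alone). Transcripts of Fos, Jun and Egr1 together were at 77.5, 289, 125 and 430.2 CPM in the 4 libraries. Regulatory T cell activation genes had medians of -0.27 and -0.37, which became 0.50 (0.18 to 0.80) and 0.20 (-0.19 to 0.44) outside the Dapl1 clusters.

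Reported targets of miR-155 in CD8 T cells were higher for 12 of 23 at day 9, with a median of 0.63 (0.33 to 0.74), and for 5 of 18 at day 12, with a median of 0.18 (-0.05 to 0.47). The list holds Ets1 at 175.6 against 192.2 CPM and Il6ra at 28.7 against 2.1 CPM at day 9, and Ifngr1 at 491.5 against 310.0 CPM. edgeR's quasi-likelihood test found that 4 of 21 rose (4 adjusted over the list alone). Genes with a miR-155 seed site in the 3' UTR were compared with all others. In all T cells at day 9 the 977 genes with a site stood 0.11 higher on the log2 scale, above 99.5% of 419 other sequences of 7 bases, and at day 12 they stood 0.01 higher, above 40.3%. CD8 T cells were 685 of 847 T cells in wild-type and 328 of 781 in knockout at day 9, so this pooled value also carries the mix of classes. The difference was 0.07 in CD8 T cells at day 9 (97.4%) and 0.04 at day 12 (74.7%), and at day 9 it was 0.04 (89.0%) against genes matched on 3' UTR length, 0.09 with 8mer sites (95.2%) and 0.09 with the last 1000 bases (95.9%). Within the Dapl1 clusters at day 9 it was 0.02 (61.8%), and within the other CD8 T cell clusters 0.01 (92.6%). In other T cells it was 0.00 at day 9 (72.3%) and -0.03 at day 12 (11.5%). Classes without the deletion were read too. NK cells had 0.00 (78.0%) and -0.02 (3.1%) at day 9 and day 12. In the same order cDC1 had -0.02 (79.0%) and -0.02 (30.5%), and cDC2 had -0.01 (81.1%) and 0.01 (33.7%). Monocytes or macrophages had -0.02 (30.5%) and 0.03 (93.6%).

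Monocytes or macrophages carry no deletion in this design, and the comparison asked whether their state differed in knockout hosts. They held less transcript of the response to interferon-gamma at both days, and less of the response to type I interferon at day 9. MHC class I genes had lower medians at both days, and MHC class II genes did so to a smaller extent. Over both days the edgeR test called 0 of 19 and 0 of 12 of them, and 16 and 2 adjusted over the list alone. Genes of alternatively activated macrophages, which go with tissue repair, were higher at both days, as was a part of the genes of lipid handling. The clusters that held these cells also differed, with Hp and Ace monocytes, Cxcl9 and Cxcl10 macrophages, and Spp1 and Trem2 macrophages mostly from the knockout library of day 9.

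The 3 clusters with Hp and Ace, with Cxcl9 and Cxcl10, and with Dct, Spp1 and Trem2 among their top 10 genes held 30.1%, 31.2% and 27.6% of knockout monocytes or macrophages at day 9. A cluster with Vcan and Mrc1 held 33.9% of wild-type and 0.943% of knockout cells at day 9, and 35.7% and 44.6% at day 12. A cluster with Gbp2b and Il18bp held 62, 4, 627 and 31 cells of the 4 libraries. The cluster with Spp1 and Trem2 also carried melanoma transcripts at 413.9 CPM, and these stood at 5.87, 225, 15.7 and 22.7 CPM over all monocytes or macrophages of the 4 libraries.

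The interferon-gamma response list in monocytes or macrophages was lower for 22 of 29 genes at day 9, with a median log2 ratio of -0.84 (-0.89 to -0.77), and for 24 of 29 at day 12, with a median of -0.97 (-1.06 to -0.82). Gbp2b was at 6.1 against 110.8 CPM at day 9 and at 6.5 against 120.1 CPM at day 12, and Psmb8, a subunit of the immunoproteasome, had log2 ratios of -0.63 and -0.75. The fall of Gbp2b, with a log2 fold change of -4.20 over both days, was far larger than the list's medians. Gbp2b thus does not stand for the list. Cxcl9 was higher in knockout at day 9, at 593 against 409 CPM, and lower at day 12, at 125 against 285 CPM. Of the type I interferon response list 21 of 22 genes were lower at day 9, with a median of -1.31 (-1.40 to -1.23), and 0 of 22 at day 12, with a median of -0.09 (-0.13 to -0.02). Isg15 was at 394 against 1291 CPM at day 9 and at 856 against 933 CPM at day 12. MHC class I genes were lower for 12 of 19 and 10 of 19, with medians of -0.75 and -0.63, among them H2-Q7 at -2.04 and -0.97. MHC class II genes were lower for 6 of 12 and 2 of 12, with medians of -0.59 and -0.26, and H2-Ab1 stood at -0.62 and -0.28. Without the cluster carrying melanoma transcripts, a choice made after the data were seen, the medians at day 9 were -0.51 for interferon-gamma, -0.91 for type I interferon and -0.81 for MHC class II. The MHC class II median at day 9 became -0.24 without doublet removal and -0.29 with mitochondrial shares up to 5%.

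Alternatively activated macrophage genes were higher for 13 of 22 at day 9, with a median of 0.85 (0.74 to 1.19), and for 18 of 25 at day 12, with a median of 0.83 (0.78 to 0.95). Arg1 was at 214.6 against 19.1 CPM at day 9, and Retnla at 1377 against 590.1 CPM and Cd209f at 70.7 against 16.6 CPM at day 12. Lipid and lysosome genes had medians of 0.49 and 0.38, with 11 and 10 of 23 higher, among them Gpnmb with a log2 ratio of 3.28 at day 9 and Fabp5 with 1.24 at day 12. Chemokine genes were higher for 7 of 18 and 8 of 19, with Ccl24 at log2 ratios of 2.49 and 1.69. Hypoxia and glycolysis genes had medians of 0.30 and 0.36, with Hilpda at 1.47 at day 9. Inflammatory macrophage genes had medians of -0.09 and -0.12, the first of which became 0.38 (0.29 to 0.51) without the cluster carrying melanoma transcripts, and Nos2 was at 1.1 against 11.3 CPM at day 12. Cell-cycle genes had a median of -0.57 at day 9, which became 0.51 with mitochondrial shares up to 5% and 0.42 without doublet removal, and of 0.05 at day 12. Over both days, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment found that 8 of 29 interferon-gamma response genes fell (23 adjusted over the list alone), 0 of 19 MHC class I genes fell (16 adjusted over the list alone), 0 of 12 MHC class II genes fell (2 adjusted over the list alone), 1 of 23 lipid and lysosome genes rose (13 adjusted over the list alone), and 4 of 25 alternatively activated macrophage genes rose (16 adjusted over the list alone). It called 0 of 22 type I interferon response genes, and 0 adjusted over the list alone. Gbp2b fell with a log2 fold change of -4.20 (adjusted p 2.70e-04 in this test) and S100a8, a neutrophil and monocyte gene, rose with 3.46 (adjusted p 2.04e-03). Gbp4, Il18bp and Iigp1, all induced by interferon, had log2 ratios from -1.71 to -1.46 at both days, and Thbs1 had 1.82 and 1.69.

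The same question was asked of dendritic cells. Both types of conventional dendritic cell held less transcript of the interferon-gamma response at both days and of the type I interferon response at day 9, as monocytes or macrophages did. MHC class II genes differed little in these 2 types. Ly6a, induced by interferon, was lower in both types.

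In cDC1 the interferon-gamma response list was lower for 11 of 29 genes at day 9, with a median of -0.47 (-0.65 to -0.37), and for 15 of 29 at day 12, with a median of -0.73 (-0.92 to -0.53). In cDC2 it was lower for 15 of 29 and 22 of 29, with medians of -0.63 (-0.74 to -0.54) and -0.86 (-1.03 to -0.75). The type I list was lower at day 9 for 16 of 21 genes in cDC1 and 21 of 22 in cDC2, with medians at day 9 and day 12 of -0.96 and -0.16 in cDC1 and of -1.35 and 0.09 in cDC2, and the cDC1 value at day 12 became 0.04 with thinned cells. MHC class I genes had medians of -0.50 and -0.29 in cDC1 and of -0.63 and -0.47 in cDC2, while MHC class II genes had 0.21 and 0.18 in cDC1 and -0.01 and 0.06 in cDC2. Ly6a was at 347 against 852 CPM and 84.2 against 419 CPM in cDC1, and at 1161 against 2848 CPM and 909 against 2217 CPM in cDC2. Il1b was higher in cDC1, at 213 against 26.7 CPM at day 9 and with a log2 ratio of 2.69 at day 12, and Irf8, which directs the making of cDC1, was level at 2227 against 2305 CPM at day 9. Ccl17 and Fabp5 were higher in cDC2, at 6.06 and 1.22 and at 2.81 and 1.40, and Il18bp and Fgl2 were lower, at -1.50 and -2.01 and at -1.35 and -1.41. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment found that 6 of 29 interferon-gamma response genes fell in cDC1 (13 adjusted over the list alone) and 6 of 29 in cDC2 (22 adjusted over the list alone), and that 0 of 20 type I genes fell in cDC1 (4 adjusted over the list alone) and 0 of 22 in cDC2 (7 adjusted over the list alone). Transcripts of T cells in cDC1 limit this class. Cd3e, Cd3g and Cd8b1 together were at 616, 80.0, 59.1 and 6.06 CPM in the 4 libraries, and the cytotoxic and effector list was lower there for 18 of 19 genes at day 9, with a median of -4.05.

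**Figure D3:**
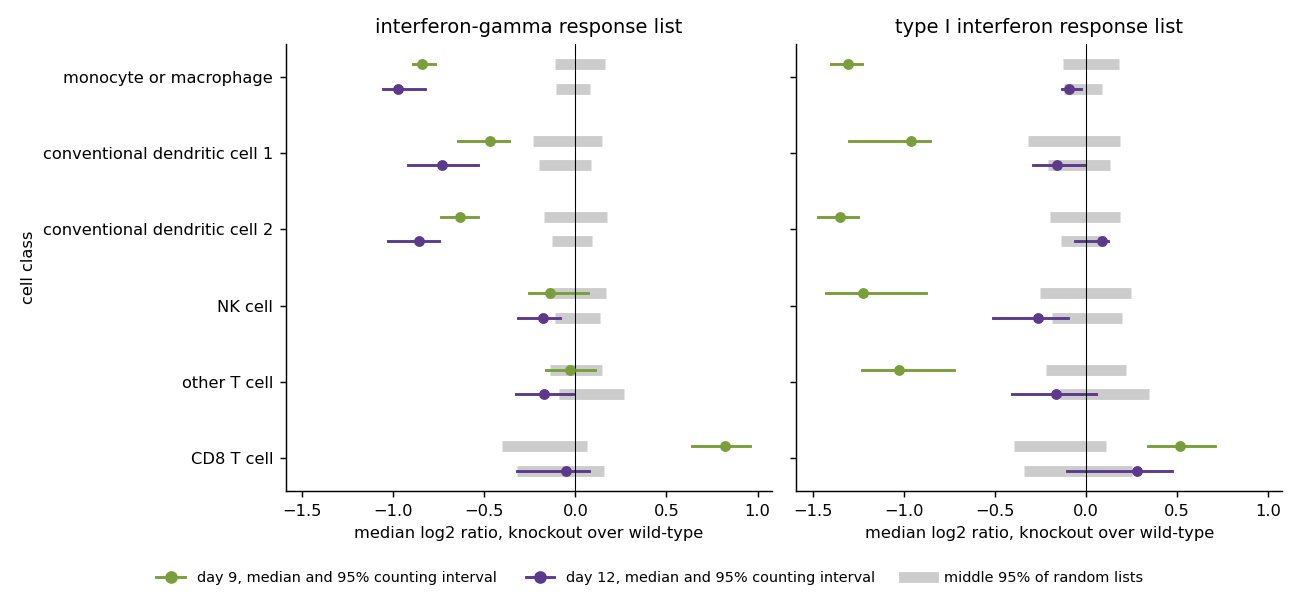
Median log2 ratio of the interferon-gamma (left) and type I interferon (right) response lists, knockout over wild-type (x axis), in 6 cell classes (y axis) at day 9 and day 12, with 95% counting intervals as lines and the middle 95% of random lists as grey bars. In monocytes or macrophages the interferon-gamma list stood at -0.84 and -0.97 and the type I list at -1.31 and -0.09.

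NK cells and other T cells were compared next. NK cells of knockout tumours held less transcript of type I interferon response at day 9 and more of the chemokines Ccl3 and Ccl4, which draw in other immune cells. Their interferon-gamma response differed little. Other T cells shared the lower type I response of day 9. Their loss of Mir155hg could not be read, as they held 1 and 4 Mir155hg UMIs in the wild-type libraries and 0 in the knockout libraries.

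In NK cells the type I list was lower for 14 of 19 genes at day 9, with a median of -1.22 (-1.43 to -0.88), and for 5 of 19 at day 12, with a median of -0.26 (-0.51 to -0.10), and Isg15 had log2 ratios of -1.63 and -0.85. The interferon-gamma list had medians of -0.14 and -0.18. Chemokine genes were higher for 6 of 8 at day 9, with a median of 1.88 (1.45 to 2.46), and had a median of -0.07 at day 12. Ccl3 was at 453 against 82.4 CPM at day 9 and at 241 against 119 CPM at day 12, and Ccl4 had log2 ratios of 2.39 and 0.79. Macrophage transcripts (C1qa, C1qb and Apoe) in NK cells were at 42.6 against 7.79 CPM at day 9 and at 93.8 against 102 CPM at day 12, and monocytes or macrophages of the knockout library at day 9 held Ccl3 at 223 CPM, less than its NK cells, and C1qa, C1qb and Apoe at 3776 CPM. Cell-cycle genes were lower for 11 of 24 at day 9, with a median of -0.42, and for 0 of 24 at day 12. Gzma, a killing enzyme, had log2 ratios of -0.74 and -0.26, and the cytotoxic and effector list had medians of 0.05 and 0.06. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment found that 3 of 18 type I genes fell (9 adjusted over the list alone) and 3 of 11 chemokine genes rose (4 adjusted over the list alone). The NK cells of the 4 libraries lay in the same 8 clusters in different shares, with 26.1% of wild-type and 4.31% of knockout NK cells at day 9 in the one with Gzma and Klra4. Their T cell transcripts were at 271, 30.0, 70.3 and 49.1 CPM.

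In other T cells the type I list was lower for 10 of 14 genes at day 9, with a median of -1.03 (-1.23 to -0.72), with Ifit3 at 26.9 against 109.5 CPM, and had a median of -0.16 at day 12. Naive and memory genes had medians of 0.16 and 0.07, and cytotoxic and effector genes of 0.05 and 0.23. Gzmc was higher, with log2 ratios of 2.27 and 2.80. The edgeR test found that 0 of 13 type I genes fell (7 adjusted over the list alone).

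Over all genes tested, edgeR's quasi-likelihood test called 527 of 8142 genes for genotype in CD8 T cells (254 higher and 273 lower), 6 in other T cells, 44 in NK cells, 121 in cDC1, 29 in cDC2 and 65 in monocytes or macrophages. DESeq2 called 111, 2, 4, 19, 17 and 97. These counts changed when the model or the libraries did. A fit to 3 libraries leaves no residual degree of freedom with the day term, so it was made without that term, and the counts below mix the effects of both. In CD8 T cells the count was 165 without the wild-type library of day 9, 717 without that of day 12, 2 without the knockout library of day 9 and 2 without that of day 12. In cDC1 it was 24, 202, 11 and 4 in the same order, in NK cells 5, 25, 9 and 11, in cDC2 4, 11, 24 and 89, in other T cells 8, 14, 9 and 19, and in monocytes or macrophages 0, 0, 4 and 151. With all 4 libraries and without the day term it was between 2 and 7 in the 6 classes.

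The genotype ratios of day 9 and day 12 were then set side by side, gene by gene. The correlation across genes, which are not independent replicates, was 0.448 in CD8 T cells, 0.351 in monocytes or macrophages, 0.233 in cDC1, 0.195 in cDC2, 0.126 in NK cells and 0.0470 in other T cells. The rank correlations were 0.397, 0.249, 0.152, 0.0989, 0.0394 and -0.0049 in the same order. Simulated counting noise alone gave at most 0.042 for the first. Genes moved in the same direction at both days for 64.5% in CD8 T cells and for 50.1% in other T cells.

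A few genes differed in T cells and non-T cells alike, and these were chosen after their values were seen. Of 6650 genes measured in at least 4 of the 6 classes at both days, 3 were at least 2-fold different in 1 direction at both days in every class that measured them, and 0 went in opposite directions at day 9 and day 12 in every such class. Rpl29 (ENSMUSG00000048758; chromosome 9, 106429454 to 106431568), a ribosomal protein gene, was at 2090.0 and 135 CPM over the 6 classes in wild-type and knockout at day 9 and at 1623 and 168 CPM at day 12. Gm10709 (ENSMUSG00000074516; chromosome 9, 7751725 to 7752204), a processed pseudogene with 99.17% of its 480 bases identical to an Rpl29 transcript, was at 26.3, 882, 12.3 and 973 CPM in the same order. Wdfy1 (ENSMUSG00000073643; chromosome 1, 79702262 to 79776143), a signalling adaptor, was at 43.1, 7.78, 50.5 and 11.6 CPM.

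**Figure D4:**
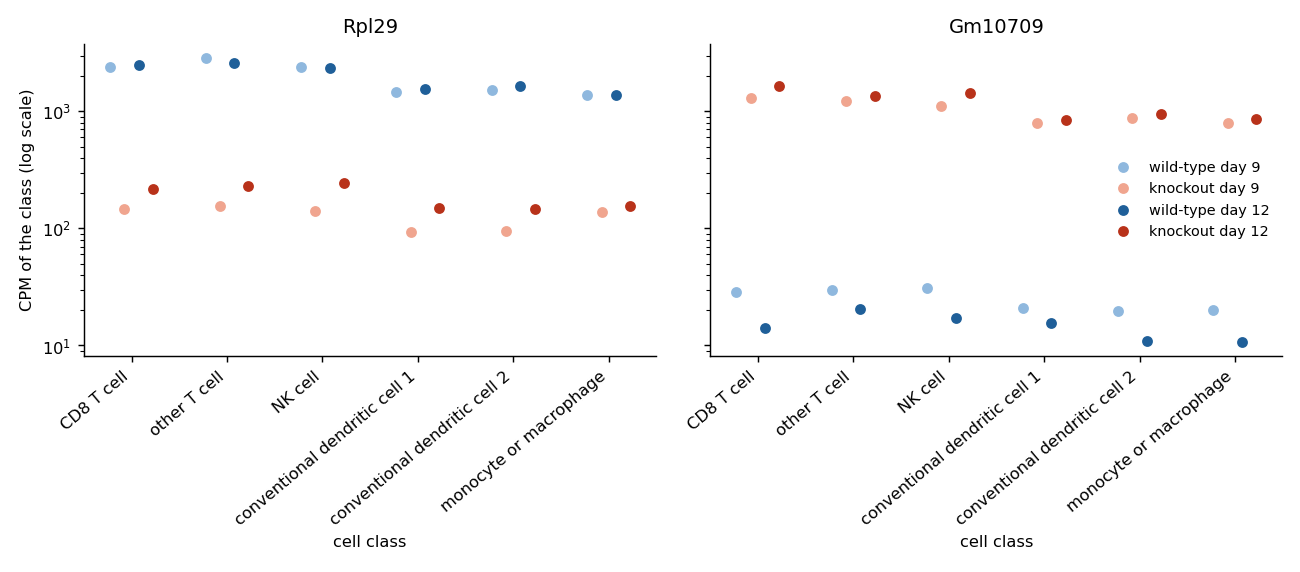
CPM of a class on a log scale (y axis) for Rpl29 (left) and its processed pseudogene Gm10709 (right) in 6 cell classes (x axis), 1 point per library. Over the 6 classes Rpl29 stood at 2090.0 and 135 CPM and Gm10709 at 26.3 and 882 CPM in wild-type and knockout at day 9.

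The last comparison asked how the infiltrate differed between day 9 and day 12 in each genotype. In wild-type tumours the CD8 T cells of day 12 held more naive and memory transcript and less of cell division and inhibitory receptors than those of day 9. Monocytes or macrophages of day 12 held more transcript of alternatively activated macrophages in both genotypes. NK cells held more cell-division transcript at day 12. The type I interferon response of myeloid cells was higher at day 12 in knockout tumours and lower or level in wild-type tumours.

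In CD8 T cells the naive and memory list had a median log2 ratio, day 12 over day 9, of 1.5 in wild-type and 0.19 in knockout, the inhibitory receptor list of -0.88 and -0.27, and the cell-cycle list of -0.61 and -0.64. The cluster with Gzmk, Pdcd1 and Tox held 36.1% of wild-type CD8 T cells at day 9 and 9.52% at day 12. The one with Gzmk, Cd8b1 and Bcl11b held 5.11% and 47.6%. A change within clusters was not told apart from this shift between them. For day, edgeR's quasi-likelihood test found that 2 of 17 naive and memory genes rose (9 adjusted over the list alone, with 1 that fell), 2 of 15 inhibitory receptors fell (7 adjusted over the list alone) and 0 of 24 cell-cycle genes fell (10 adjusted over the list alone). Penk was higher at day 12, with log2 ratios of 2.92 and 2.24, and Spp1 and Rgs16 were lower, at -3.75 and -3.36 and at -2.07 and -2.01. In NK cells the cell-cycle list had medians of 0.43 and 0.99, with 7 and 18 of 24 genes higher, and edgeR's quasi-likelihood test found that 11 of 24 rose (16 adjusted over the list alone), among them Hist1h1b with log2 ratios of 2.05 and 2.67. In monocytes or macrophages the alternatively activated list had medians of 1.24 and 0.80, and the test found that 8 of 25 rose and 1 fell (15 and 3 adjusted over the list alone). Retnla was at 590.1 against 2.57 CPM in wild-type and at 1377 against 4.05 CPM in knockout, Folr2 had log2 ratios of 4.02 and 5.33, and Ccl8, a chemokine, 3.04 and 4.27, while Gsr had -2.86 and -2.93. A cluster with Lyve1, Cd209f and Folr2 held 0, 1, 82 and 88 cells. The type I list had medians of -0.31 and 0.97 in monocytes or macrophages, of -0.19 and 0.73 in cDC1 and of -0.71 and 0.65 in cDC2. The interferon-gamma list had medians of -0.51 and -0.65 in cDC1 and of -0.44 and -0.91 in cDC2. The clusters of cDC2 differed between days, as the one with Retnla and Fcrls held 14.0% and 3.70% of them in wild-type and knockout at day 9 and 33.5% and 45.4% at day 12. In cDC2 Ccl2 was higher, with log2 ratios of 2.36 and 2.65, beside macrophage transcripts (C1qa, C1qb and Apoe) at 270.4 and 120.4 CPM in wild-type and knockout at day 9 and at 814 and 487 CPM at day 12. Other T cells had more Cd74, at 2.05 and 1.74, beside these macrophage transcripts at 16.6 and 34.6 CPM at day 9 and at 100.4 and 110.0 CPM at day 12. Macrophage transcripts in CD8 T cells differed too, as C1qa, C1qb and Apoe together were at 7.73 and 37.3 CPM in CD8 T cells at day 9 and at 106 and 104 CPM at day 12.

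Over both genotypes the test called 42 genes for day in CD8 T cells, 90 in other T cells, 630 in NK cells, 248 in cDC1, 197 in cDC2 and 396 in monocytes or macrophages, and DESeq2 called 14, 6, 18, 22, 45 and 261. Of the 630 in NK cells, where edgeR pooled variation over genes, DESeq2 also called 18 in the same direction. Day and preparation run cannot be told apart in these libraries.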

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

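The test of a strain variant or of shared reads for the interferon-gamma list, the medians outside the Dapl1 clusters, the medians without the cluster carrying melanoma transcripts, the regulatory T cell shares with an unnamed cluster, and the choice of Rpl29, Gm10709 and Wdfy1 came after the results were seen.

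Several results drew attention because the knockout stood on opposite sides of the wild-type at day 9 and day 12. The differences between days were not tested, as each day had 1 library per genotype. The share of mature dendritic cells, knockout over wild-type, was 0.651 at day 9 and 2.80 at day 12. In CD8 T cells the chemokine list had a median log2 ratio of 1.57 at day 9 and of -1.08 at day 12. Ccl3, Ccl4 and Ccl5 had ratios of -2.70, -1.91 and -1.12 at day 12, and Cxcl9 one of 3.65 at day 9. In other T cells the inhibitory receptor list had medians of -0.40 and 0.62 and the hypoxia and glycolysis list of -0.19 and 0.47. In NK cells the MHC class II list had medians of 0.28 and -0.21, and the hypoxia and glycolysis list of -0.53 and 0.33. How much of the Cxcl9 and MHC class II transcript in lymphoid cells came from myeloid cells was not estimated. C1qa, C1qb and Apoe in CD8 T cells stood at 7.73, 37.3, 106 and 104 CPM in the 4 libraries.

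The first pattern weighed was the CD8 T cells of knockout tumours, with less cell-cycle, cytotoxic and inhibitory receptor transcript and more naive transcript. With every cell thinned to 2500 UMIs, at least 131% of each of the 3 lower medians of day 9 remained. Random thinning leaves a gene's expected share of a cell's UMIs unchanged and mainly gives cells equal weight. It therefore cannot decide whether shallower knockout cells are a cause. A shift between clusters of CD8 T cells stays open, since as little as 20.1% of a median (cell cycle) remained outside the Dapl1 clusters, while the clusters were made from these same genes. A biological explanation in the design, the loss of miR-155 in T cells, also stays open and may act through how many antigen-experienced cells enter or divide, or through their state. Dissociation and stress genes were also higher, with medians of 0.64 and 0.82 outside the Dapl1 clusters, so a difference in cell handling was not excluded. The pools of each genotype and day, and their preparation, cannot be told apart from it with 1 library each.

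The second pattern was the lower interferon-gamma response list in monocytes or macrophages and conventional dendritic cells. A strain variant or reads shared between copies, if acting in every class, would lower the list in each by about as much. Its median in CD8 T cells at day 9 was 0.82, and 0.00 (-0.16 to 0.16) outside the Dapl1 clusters, against -0.84 in monocytes or macrophages. At day 12 the median in CD8 T cells was -0.25 (-0.62 to -0.07) outside the Dapl1 clusters, against -0.97 in monocytes or macrophages. These values argue only against a variant that acts alike in every class as the whole cause. They concern the list's median and cannot speak to a single member such as Gbp2b. A variant acting in myeloid cells alone stays open. Macrophage transcripts were higher in knockout CD8 T cells at day 9, so a lowering there could be masked. Thinning kept 76.0% or more of the median in monocytes or macrophages. Random thinning leaves expected shares of a cell's UMIs unchanged, so this does not decide on depth as a cause. Within clusters of monocytes or macrophages the median over clusters kept as little as 27.2% of the class's value, which leaves a shift between clusters open because these genes shaped the clusters. At day 12 the list was below 0 with its counting interval in 7 of 8 clusters, from -1.29 in the one with Arg1 and Vegfa to -0.15, and stood at -0.04 (-0.10 to 0.14) in the one with Gbp2b. At day 9 it was so in 1 of 2 clusters. Less Ifng transcript in the knockout libraries is a candidate explanation, as Ifng over all kept cells had log2 ratios of -2.23 (-2.32 to -2.13) at day 9 and -2.43 (-2.61 to -2.25) at day 12, with CD8 T cells giving 82.5%, 81.7%, 87.5% and 22.3% of Ifng UMIs in the 4 libraries. As a share of the UMIs of CD8 T cells, Ifng stood higher in knockout at day 9, at 489 against 315 CPM. By count, 328 knockout CD8 T cells held 1022 Ifng UMIs and 685 wild-type cells held 3135, so each knockout cell held fewer. Knockout CD8 T cells had a median of 4923 UMIs at that day, against 12146 in wild-type. The lower Ifng value over all cells at day 9 thus goes with a smaller share of CD8 T cells and with fewer UMIs in each.

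The third pattern was Rpl29 and Wdfy1 lower and Gm10709 higher in every class. Reads moved between Rpl29 and its processed pseudogene by a variant of the knockout mice are a candidate explanation, since the log2 ratio of Gm10709 over Rpl29 in knockout libraries had an SD of 0.277 over classes and days, under the 0.404 of Rpl29 itself in wild-type libraries. The sum of both genes in knockout was 0.479 to 0.750 of that in wild-type, so moved reads alone leave a part uncounted. In classes that had not been used to pick it, Rpl29 was at least 2-fold lower in 100% of 10 pairs of class and day, which goes with a difference in every cell and not in T cells alone. These classes are other cells of the same pools, so they are not an independent test of a variant. Genotypes of the mice are not given in the labels beyond the conditional knockout, and no biological effect of these genes was tested.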

How the results depend on the processing

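CD8 T cells outside the Dapl1 clusters, monocytes or macrophages without the cluster carrying melanoma transcripts, and regulatory T cells with an unnamed cluster were chosen after seeing the data; the other settings were planned. No paired analysis was possible because the labels match nothing between genotypes beyond the day, which was a term of the test. Where a value below differs, the cause was not tested, except that fewer libraries or another gene filter change the counts by construction.

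The leading gene lists kept their direction in 140 of 140 planned and the sign of the median in 16 of 16 added alternatives, but outside the Dapl1 clusters at day 12 the counting intervals of inhibitory receptors (-0.44 to 0.40) and naive genes (-0.06 to 0.69) span 0. All lists kept the sign in 1304 of 1419 and 57 of 68, and the leading share ratios in 90 of 98. The CD8 T cell share ratio ranged from 0.207 to 0.285 at day 9 and from 0.424 to 0.552 at day 12, and that of monocytes or macrophages from 3.30 to 3.51 at day 9. Over planned settings the interferon-gamma list in monocytes or macrophages ranged from -0.87 to -0.64 at day 9 and from -1.01 to -0.87 at day 12. Asking for 500 genes per cell left all shares as they were, and TMM factors cannot move a correlation, so neither says anything about stability. Resolutions 0.5 and 2 changed the first clustering alone. The shares of T cell classes and NK cells were thus not tried at another resolution of their own clustering. TMM and median-of-ratios factors move all log2 ratios of a comparison alike. Their shifts were small beside most leading medians and could hardly have turned them.

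Among share ratios, naming each cell by its own markers gave 0.285 for CD8 T cells, 0.451 for cDC1, 1.56 for cDC2 and 0.742 for CD4 T cells at day 9 (main values 0.231, 0.179, 1.12 and 2.60), and 0.766 for cDC1 at day 12. Leaving cell-cycle genes out of clustering gave 0.879 for other T cells at day 12, and mitochondrial shares up to 5% gave 0.811 for cDC2 at day 12. The unnamed cluster with Foxp3 took the ratio for regulatory T cells at day 9 from 0.180 to 0.333.

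With TMM factors the naive list in CD8 T cells at day 9 was at 3.06, the MHC class I list there at 0.0044 and the MHC class II list in monocytes or macrophages at day 12 at -0.28. Median-of-ratios factors gave -1.41 for cell cycle, -0.83 for cytotoxic, 3.12 for naive and 0.0671 for MHC class I genes in CD8 T cells at day 9, and -0.61 for MHC class II in monocytes or macrophages at day 9.

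The mean over cells gave -2.37 for cell cycle, -1.24 for cytotoxic, -1.97 for inhibitory receptor and 2.32 for naive genes in CD8 T cells at day 9. In monocytes or macrophages it gave -0.68 for interferon-gamma, -1.06 for type I and -0.67 for MHC class II genes at day 9, and 0.77 for alternatively activated genes at day 12.

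Thinned cells gave -2.28, -1.28, -1.88 and 2.45 for these CD8 T cell lists at day 9, -1.13 for cell cycle at day 12 and -0.39 for inflammatory macrophage genes at day 9. They gave -2.98 for chemokine and -0.10 for lipid and lysosome genes in cDC1 at day 9, 0.0423 for type I genes in cDC1 at day 12, and -0.48 for interferon-gamma at day 9 and -0.0027 for chemokine genes at day 12 in cDC2. In monocytes or macrophages they gave -0.64 for interferon-gamma, -1.15 for type I and 0.34 for inhibitory receptor genes at day 9, and 0.0254 for cytotoxic and 0.78 for alternatively activated genes at day 12. Members with at least 5 UMIs gave -0.0216 for inflammatory macrophage genes in cDC2 at day 9.

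With mitochondrial shares up to 5%, CD8 T cells had -0.37 for type I genes at day 9 and -1.27 for cytotoxic genes at day 12. At day 9 cDC1 had -0.0238 for alternatively activated and -0.0507 for lipid and lysosome genes, and cDC2 had 0.87 for regulatory T cell activation genes, with -0.63 for interferon-gamma at day 12. Monocytes or macrophages had 0.51 for cell cycle and -0.29 for MHC class II genes at day 9, and -0.13 for type I and -0.19 for MHC class II genes at day 12. Genotype calls were 857 in CD8 T cells, 17 in NK cells, 137 in cDC2 and 109 in monocytes or macrophages.

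Without doublet removal, CD8 T cells had -0.47 for type I and 3.02 for naive genes at day 9 and -1.24 for cytotoxic genes at day 12. At day 9 cDC1 had -0.72 for chemokine genes and cDC2 0.44 for regulatory T cell activation genes, with -0.72 for interferon-gamma at day 12. Monocytes or macrophages had 0.42 for cell cycle and -0.24 for MHC class II genes at day 9, and -0.18 for MHC class II and 1.01 for alternatively activated genes at day 12. Genotype calls were 10 in other T cells, 26 in NK cells, 49 in cDC1, 18 in cDC2 and 237 in monocytes or macrophages.

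Outside the Dapl1 clusters, CD8 T cells at day 9 had -0.31 for cell cycle, -0.36 for cytotoxic, -0.37 for inhibitory receptor, 1.65 for naive, -0.75 for type I, 0.0769 for hypoxia and 0.50 for regulatory T cell activation genes. At day 12 they had -0.61, -0.56, -0.0145 and 0.25 for the first 4 lists, 0.20 for regulatory T cell activation and 0.0575 for respiratory chain genes. Without the cluster carrying melanoma transcripts, monocytes or macrophages at day 9 had -0.51 for interferon-gamma, -0.91 for type I, -0.81 for MHC class II and 0.38 for inflammatory macrophage genes.

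Counting members at least 2-fold in place of 1.5-fold gave 4 of the inhibitory receptors lower in CD8 T cells and 12 of the interferon-gamma genes lower in cDC2, both at day 12. In monocytes or macrophages it gave 10 and 14 interferon-gamma genes lower at day 9 and day 12, 2 MHC class II genes lower at day 9, 0 type I genes lower at day 12 and 10 alternatively activated genes higher at day 12.

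Genotype calls by DESeq2 were 111 in CD8 T cells, 2 in other T cells, 4 in NK cells, 19 in cDC1 and 17 in cDC2, and day calls were 14, 6, 18, 22 and 45, with 261 in monocytes or macrophages. Genes called for genotype by both tools numbered 111 in CD8 T cells and 60 in monocytes or macrophages. Median-of-ratios factors in edgeR gave 15 genotype calls in other T cells and 25 in monocytes or macrophages, and 149 day calls in CD8 T cells and 167 in other T cells. With no gene filter but at least 1 UMI, genotype calls were 819 in CD8 T cells, 14 in other T cells, 200 in cDC1, 145 in cDC2 and 533 in monocytes or macrophages, and day calls 242, 159, 401, 508 and 1284. Without the day term genotype calls were 7, 2, 2, 2, 2 and 4 in CD8 T cells, other T cells, NK cells, cDC1, cDC2 and monocytes or macrophages.

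Leaving out each library in turn and the day term with it, with the lone library of a group assumed to vary like the others, gave from 2 to 717 genotype calls in CD8 T cells, 8 to 19 in other T cells, 5 to 25 in NK cells, 4 to 202 in cDC1, 4 to 89 in cDC2 and 0 to 151 in monocytes or macrophages.

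Correlations of genotype ratios between days over genes with at least 100 UMIs at each day were 0.589 in CD8 T cells, 0.204 in other T cells, 0.226 in NK cells, 0.330 in cDC1, 0.332 in cDC2 and 0.425 in monocytes or macrophages, with rank correlations of 0.524, -0.0995, -0.0081, 0.183, 0.168 and 0.287. With 8mer sites alone the seed difference in all T cells at day 9 was 0.11, above 95.7% of other sequences and so no longer beyond the middle 95%. CD8 T cells of the knockout library at day 12 had the fewest UMIs of the 6 classes, 316162 from 55 cells. Simulated 2-fold changes were found for 83% of genes in CD8 T cells and 87% in other T cells with a dispersion of 0.01 and for 0% in both with 0.1, so this follows the dispersion. The square root of the fitted common dispersion ranged over the 6 classes from 0.12 in other T cells to 0.164 in CD8 T cells. These fitted dispersions lie between the simulated ones, so neither setting gives the power in these data.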

Other observations

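Mature dendritic cells, which had fewer than 50 cells in 1 library and no gene lists at day 9, could be read at day 12. Their interferon-gamma response list was lower for 17 of 27 genes in knockout, with a median log2 ratio of -0.76, and their MHC class II list had a median of -0.47. Hypoxia and glycolysis genes had a median of 0.49. The Mir155hg transcript stood at 40.5 CPM (30.9 to 52.0) in mature dendritic cells of the knockout library at day 12 and at 21.7 CPM (12.8 to 34.2) in the wild-type library.

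Between day 9 and day 12, 7 genes differed at least 2-fold in 1 direction in both genotypes in every class that measured them, and they were chosen after their values were seen. Ccl8, Retnla, AY036118 and Gm26917 were higher at day 12, and Fam107b, Il10ra and Jak3 were lower. AY036118 and Gm26917 are annotated as long noncoding and lie side by side on chromosome 17. What RNA their UMIs stem from was not tested. Retnla and Ccl8 stood at 590.1 and 669 CPM in wild-type monocytes or macrophages at day 12 and at 29.9 and 19.7 CPM in NK cells, where macrophage transcripts (C1qa, C1qb and Apoe) went from 7.79 to 102 CPM between the days, so these 2 cannot be read as a change of NK cells' own transcript. Jak3, a kinase of cytokine receptors, stood at 35.3, 13.8, 8.14 and 5.87 CPM over the 6 classes in wild-type and knockout at day 9 and wild-type and knockout at day 12. Class shares differ between the libraries, so these pooled values also carry the mix of cells.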
